A study of Homo sapiens with 2 samples.

How the data were processed

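U2AF2 eCLIP libraries from 2 biological replicates of HEL cells were analysed. Per the labels' protocols, cells were crosslinked with ultraviolet light, lysed, sonicated and treated with RNase I, U2AF2 was immunoprecipitated, an RNA linker was ligated, the complexes were excised from a membrane and the recovered RNA was reverse transcribed and sequenced with paired ends. Per the submitters' processing notes, cutadapt, STAR 2.7.0f and the genome build GRCh38.p10 were used. The deposited table held raw counts per gene, as whole numbers, for both libraries. It also held tallies of reads on no feature, ambiguous reads, multimapping reads and unmapped reads, under the names that STAR's gene counting gives them. The counting step, its strand setting, the annotation release, the removal of PCR duplicates and the use of molecular identifiers were not given in the sources used here. Duplicates left in would make counting intervals too narrow, and a count taken without strand or on one strand changes which overlapping gene receives a read.

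The tallies were left out of library sizes and tests. Replicate 1 held 36374618 reads on no feature, 17816 ambiguous, 12801960 multimapping and 7864648 unmapped reads, and replicate 2 held 50621073, 23938, 16503606 and 11108587. Multimapping reads were 21.4% ± 0.934 (SD, n = 2) and unmapped reads 13.8% ± 0.288 of all reads. In replicate 1 the gene share of uniquely mapped reads was 2.66% (exact 95% binomial interval 2.66 to 2.67) and in replicate 2 it was 2.60% (2.59 to 2.60). All columns of the table belonged to the 2 libraries.

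Genes were matched by Ensembl identifier without version to GENCODE 29 (GRCh38), which may differ from the annotation behind the counts. Of 58347 genes, 58084 (99.5%) had a model, and the 263 without one held 1.05% of the counts. Gene symbols, classes, spans, exon unions and coordinates came from that annotation, with older symbols matched through a table of gene names. Intron number was the number of gaps left after merging the exons of all transcripts of a gene. An intron covered by an exon of another transcript was therefore not counted. Single-exon genes were those whose merged exons left no gap. For each gene, other genes whose span covered any base of its exons were recorded by strand. Y-linked genes and XIST were left out of the named genes, the gene lists, and the comparisons by strand, partner and gene structure. They stayed in the library totals, the class and top-gene shares, the number of genes detected and the comparison of replicates.

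Library sizes were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, giving factors of 1.01 for replicate 1 and 0.987 for replicate 2. CPM is the count per 1e+06 scaled gene counts, and log2 CPM used a prior count of 2. Genes with at least 10 counts in each library entered the comparison of replicates. The biological coefficient of variation came from an intercept-only design. Each gene was tested between the libraries with an exact, two-sided conditional binomial test and Benjamini-Hochberg adjustment at 0.05. With 1 group no replicated test between groups existed, so the quasi-likelihood test of edgeR was not used. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures used matplotlib 3.10.9.

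The 23 gene lists were fixed before the data were examined. They covered 3' splice site recognition, SR proteins, hnRNP proteins, stress granule proteins, markers of erythroid, megakaryocyte, monocyte and granulocyte, T and B cells, neuronal and hepatocyte genes, myeloid malignancy drivers, genes with splicing changes reported in U2AF1-mutant cells, nonsense-mediated decay factors, intronless genes, ribosomal proteins, histones, mitochondrial mRNAs, mitochondrial rRNAs and tRNAs, snRNAs, snoRNAs with scaRNAs, other small RNAs and long non-coding RNAs. The median log2 CPM of each of 18 coding lists, over all members without a count filter, was set against 10000 random lists drawn from 10 bins of gene span, two-sided, with Benjamini-Hochberg adjustment over the lists. Lineage pairs and single-exon against multi-exon genes were compared by two-sided permutation with 100000 resamples. List and permutation p values run over genes, which are not independent replicates.

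The named genes followed a rule fixed in advance: the 15 protein-coding genes and the 10 other genes, with or without a model, with the highest mean log2 CPM, the 10 multi-exon protein-coding genes with the most counts per kb of span and at least 50 counts in each library, the 3 highest and the lowest member of each list, 4 genes of the U2AF family, and the 5 genes in each direction with the largest ratio between replicates past the threshold and at least 50 counts in either library. Genes outside it are marked where they appear, and not every gene the rule gave is reported here. Opposite-strand partners were named for the genes they overlap.

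Counts were also read by the gene on the opposite strand. The whole counts of genes whose exons met exactly 1 opposite-strand gene, and that a protein-coding one, were summed by that partner. Partners with at least 100 bases of counted exon within them were kept, and the sum was divided by those bases. Reads on exons beyond the partner were included, so these counts per kb are too high where a counted gene extends past it. List medians of partners were set against 10000 random draws from all partners, without matching. For splice sites, genes with at least 90% of their exon bases within the partner were sorted by whether their exons met the 40 intronic bases beside a 3' splice site or a 5' splice site of the partner.

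Steps were tested on simulated data. Coefficients of variation of 0.05, 0.1 and 0.3 were recovered as 0.0497, 0.0982 and 0.297 over 8983 genes. In the comparison of replicates, with 200 changed genes among 8983, the binomial test recovered 15% of genes at 1.5-fold with 0 false calls, 50.5% at 2-fold with 10 and 92% at 4-fold with 10. The list test called 2% of 100 unshifted lists of 24 genes and 43% of lists shifted by 1 on the log2 scale, so it misses many shifts of that size. Alternatives covered the count filter, DESeq2 1.42.0 size factors and dispersions, plain library totals, removal of mitochondrial and small RNA genes, the prior count, the matching of random lists, per-kb levels and each replicate left out. Genome sequence, input libraries and peaks were not analysed here.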

Results

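U2AF2 is the large subunit of the splicing factor U2AF and binds the polypyrimidine tract beside 3' splice sites. RNA crosslinked to U2AF2 was profiled by eCLIP, in which RNA fixed to a protein by ultraviolet light is recovered with an antibody and sequenced, in HEL, a human erythroleukemia cell line with erythroid and megakaryocytic features. The samples formed 1 group of 2 biological replicates. Input and control libraries were not analysed here, so levels were compared between genes and between the replicates, and no value is an enrichment over input. Replicate 1 held 995428 counts on genes and replicate 2 held 1350116. Genes received 2.63% ± 0.0465 (SD, n = 2) of the uniquely mapped reads, and 97.3% ± 0.0477 (SD, n = 2) were tallied as lying on no feature by a count whose strand setting is not given. A count of 0 allowed a level of up to 3.01 CPM (counts scaled to library size) in replicate 1 and 2.22 CPM in replicate 2, from 3 counts of each total. Intervals and floors cover counting error only.

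The first question was which genes held the reads. The protein-coding gene with the most counts was MFSD11, at 4250 ± 310 CPM (SD, n = 2), followed by the giant muscle protein gene TTN at 4118 ± 282 CPM, the DNA glycosylase gene NEIL1 at 3738 ± 57.7 CPM and PAQR3 at 2727 ± 9.66 CPM. Among non-coding genes the antisense RNA AL135999.1 led with 5497 ± 186 CPM, and the antisense RNAs AC037198.2 and AC006064.4 held 4471 ± 115 and 3588 ± 268 CPM. The gene ENSG00000259279.1, which has no model in the annotation used here, held 5352 ± 419 CPM. All these values are means over the 2 libraries with their SD.

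Most of these genes lay across the exons or introns of a protein-coding gene on the other strand. MFSD11 (chromosome 17, 76735865 to 76781449, plus strand, GRCh38) overlaps SRSF2, an SR splicing factor gene. NEIL1 lies opposite MAN2C1, PAQR3 opposite BMP2K, and DONSON, at 2102 ± 101 CPM (SD, n = 2), opposite SON, an SR-related protein gene. AC037198.2 (chromosome 15, 39588357 to 39588882, minus strand) lies within THBS1, the thrombospondin 1 gene. AC006064.4 (chromosome 12, 6537794 to 6538370, minus strand) lies within GAPDH, a glycolytic enzyme gene. AL135999.1 lies opposite AP1G2, and C5orf66, at 3207 ± 81.0 CPM (SD, n = 2), opposite H2AFY, a histone variant gene. Of the 15 protein-coding genes with the most counts, 13 had a protein-coding gene on the opposite strand over their exons. TTN had none and overlaps the antisense RNA TTN-AS1. Of the 10 leading other genes, 9 had such a partner, and ENSG00000259279.1 could not be assessed, since it has no model here.

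**Figure D1:**
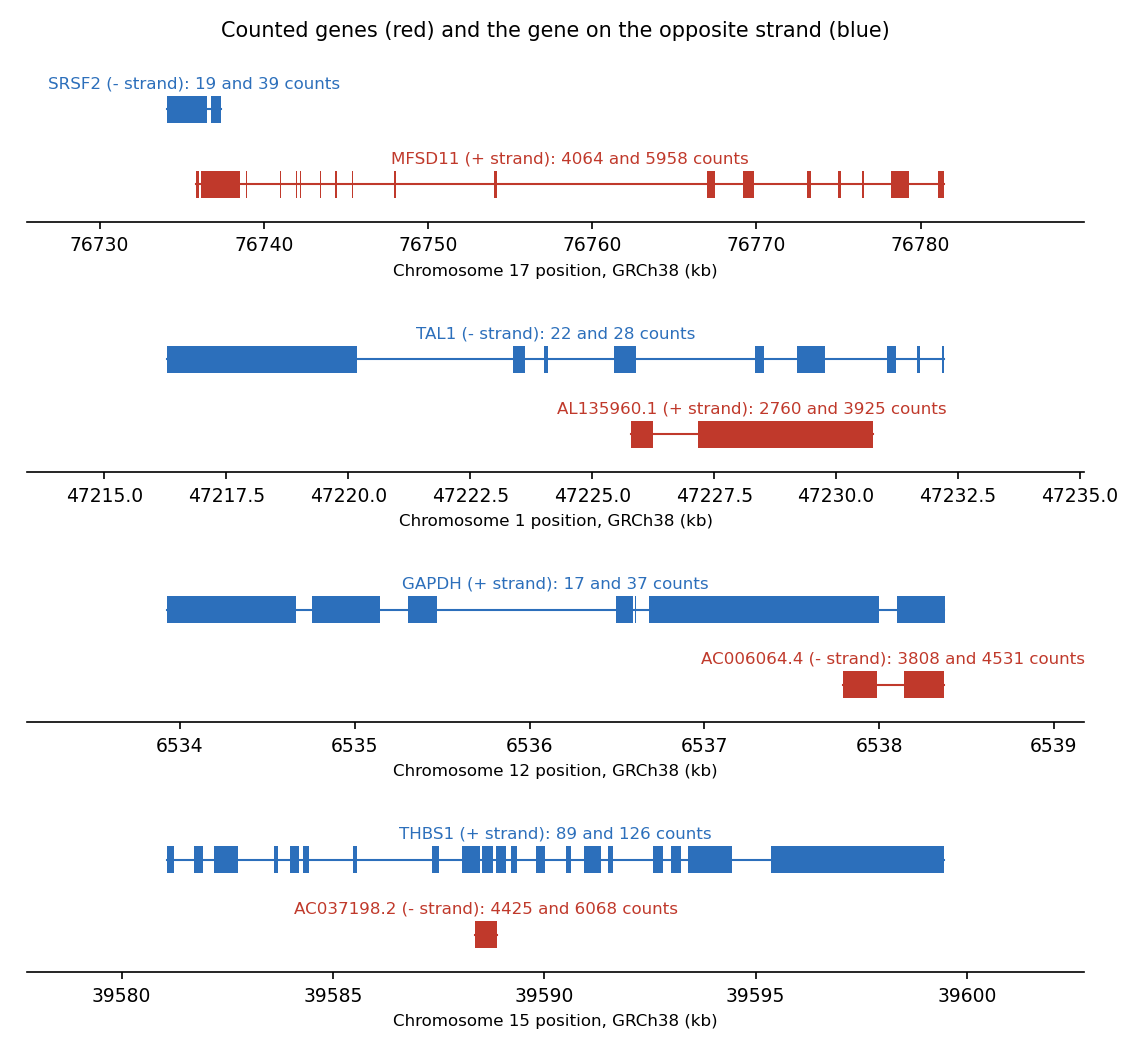
Maps of 4 loci on GRCh38 (horizontal axis, chromosome position in kb), with exons as boxes, the counted gene in red and the gene on the opposite strand in blue; labels give the counts in replicate 1 and replicate 2. AC006064.4 held 3808 and 4531 counts within GAPDH, which itself held 17 and 37, and AL135960.1, chosen after its values were seen, held 2760 and 3925 within TAL1, which held 22 and 28.

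Several genes whose RNA is abundant in most cells held few counts of their own. ACTB, the beta-actin gene, held 0 counts in both libraries, GAPDH 17 and 37, the elongation factor gene EEF1A1 8 and 6, and the long non-coding RNA MALAT1 11 and 13. These 4 genes were chosen after their values were seen. Of the U2AF family, U2AF2 itself held 18 and 30 counts, U2AF1 0 and 0, U2AF1L4 1 and 2, and ZRSR2 2 and 0. Reads mapping to several places are outside these counts, so a count of 0, as for U2AF1, need not mean that no read came from a gene. When ranked by counts per kb of gene span, the leading multi-exon protein-coding genes were AC005551.1 with 1565 counts per kb over both libraries, LRRC24 with 992 and NEIL1 with 863. LRRC24 lies opposite LRRC14, and 8 of the 10 genes of this ranking had an opposite-strand protein-coding gene, the exceptions being AC005551.1 and SRPK3, a kinase gene. The strand setting of the counting was not given in the sources used here, so for any gene taken alone it is uncertain which strand its reads came from. For a gene with an opposite-strand partner, named here or not, it is uncertain which of the 2 genes they came from. The strand comparison below, with a ratio of 45.0 for single-exon non-coding genes as a set, leaned toward the opposite strand. It does not settle this for a single gene.

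Altogether 8983 genes held at least 10 counts in each library. Protein-coding genes took 52.6% ± 0.282 (SD, n = 2) of the counts and antisense RNAs 30.3% (30.5% in replicate 1 and 30.1% in replicate 2), although antisense RNAs made up 9.34% of the genes in the table. Pseudogenes took 6.80% ± 0.0314, other long non-coding RNAs 5.33% ± 0.0595, small non-coding RNAs 0.895% ± 0.0151 and genes of the mitochondrial genome 0.540% ± 0.0254. The 10 genes with the most counts held 4.07% ± 0.0416 of all counts, the top 100 held 19.1% ± 0.0423 and the top 1000 held 55.5% ± 0.00156, each as SD over the 2 libraries.

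The position of each gene relative to protein-coding genes on either strand was then compared with its counts. Genes with a protein-coding gene over their exons on the opposite strand only held 69.2% ± 0.325 (SD, n = 2) of the counts, and genes with one on the same strand only held 2.89% ± 0.0397. Single-exon non-coding genes averaged 91.0 counts per kb over both libraries where the protein-coding gene lay on the opposite strand (2893 genes) and 2.02 where it lay on the same strand (1900 genes). The ratio of these means was 45.0 (95% bootstrap interval 34.3 to 60.6), with 45.8 in replicate 1 and 44.4 in replicate 2, and the permutation p was 1e-05, the smallest that 100000 resamples can give. Processed pseudogenes showed the same order, with a mean of 59.6 counts per kb opposite to a protein-coding gene and 2.11 on the same strand. Among protein-coding genes, the median was 40 counts over both libraries for 3958 genes with another protein-coding gene on the opposite strand only. It was 13 for 494 genes with one on each strand and 3 for 13385 genes with no other protein-coding gene over their exons. This comparison was chosen after the leading genes were seen, and genes are not independent replicates.

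**Figure D2:**
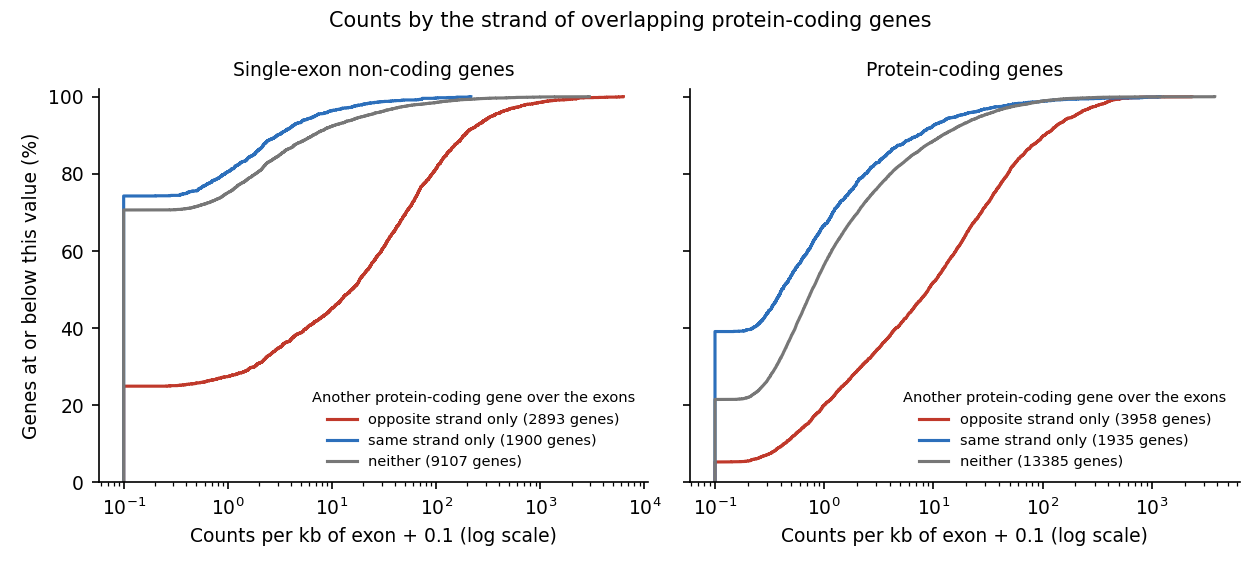
Cumulative share of genes (vertical axis, %) by counts per kb of exon over both libraries plus 0.1 (horizontal log axis), for single-exon non-coding genes on the left and protein-coding genes on the right, split by the strand of any other protein-coding gene over their exons. In both panels the curve for opposite-strand overlap lies to the right of the others, and 25.0% of single-exon non-coding genes with it held 0 counts against 74.3% with same-strand overlap.

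Agreement between the replicates was the next comparison. The leading genes kept similar levels in both libraries, for example 4389 and 4552 CPM for AC037198.2. Exceptions with more counts in replicate 2 were ONECUT3, a homeobox transcription factor gene, with 230 and 1022 counts, and ZNF773, a zinc finger gene, with 715 and 2023. The exact binomial test at the scaled library sizes gave adjusted p values (Benjamini-Hochberg) of 9.91e-73 for ONECUT3 and 6.89e-72 for ZNF773. AL592166.1, an antisense RNA that lies opposite KIF2C, was higher in replicate 1, with 1593 and 1616 counts and an adjusted exact p of 9.56e-11. CREB3, opposite GBA2, was also higher in replicate 1, with 124 and 98 counts and an adjusted exact p of 0.0320.

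Across the 8983 genes, log2 CPM correlated with a Pearson r of 0.977 (95% bootstrap interval 0.976 to 0.979) and a Spearman rho of 0.959 (0.956 to 0.962), computed across genes, which are not independent. The common biological coefficient of variation from edgeR was 6.63%, while DESeq2 gave a median coefficient of 0.252 over genes. The exact binomial test called 45 genes, 10 higher in replicate 1 and 35 higher in replicate 2, and 769 had an unadjusted p below 0.05. Of the 3704 genes with at least 50 counts in each library, 4 differed by more than 2-fold, all higher in replicate 2. They were ONECUT3, ZNF773, SCAP and LINC01342, of which ZNF773, SCAP and LINC01342 were chosen after their values were seen. The test compares 2 libraries of 1 group and covers counting error only.

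**Figure D3:**
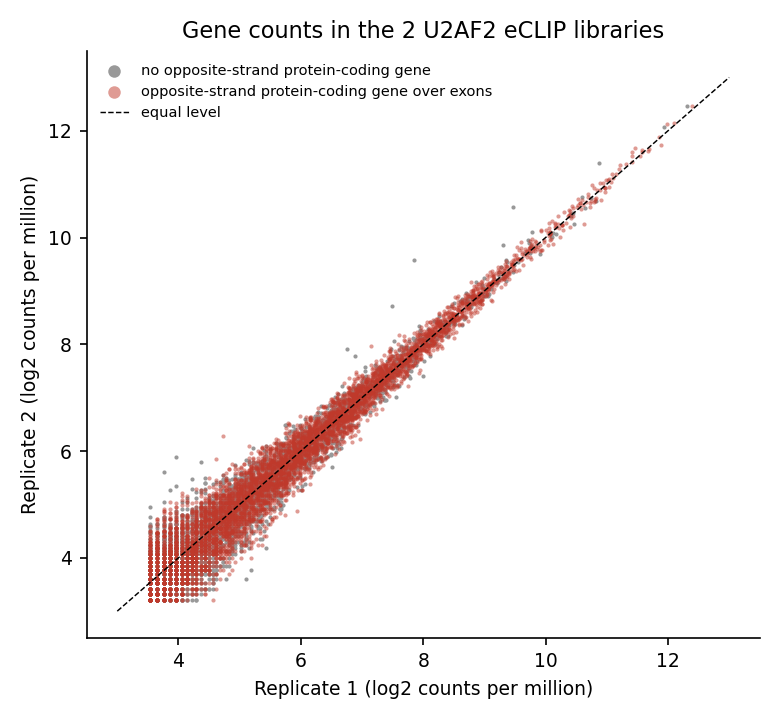
Levels in replicate 1 (horizontal axis) and replicate 2 (vertical axis) as log2 CPM with a prior count of 2. Points are genes with at least 10 counts in each library, without Y-linked genes and XIST. Red points have a protein-coding gene on the opposite strand over their exons, grey points do not, and the dashed line marks equal levels. The points follow the line, with a Pearson r of 0.977 over all 8983 genes that passed the filter. ONECUT3 and ZNF773 are among the grey points above it.

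Gene lists fixed before the data were examined were then compared with random lists of protein-coding genes matched on gene span. The 13 mitochondrial mRNAs stood above them, with a median of 7.25 log2 CPM against 1.04 for random lists and an adjusted permutation p of 0.0036. MT-ND5 led this list with 1727 ± 107 CPM (SD, n = 2), followed by MT-ND6 with 848 ± 9.99 CPM and MT-ND4 with 666 ± 6.83 CPM, all subunits of respiratory complex I, and MT-ATP8 was lowest with 26.3 ± 2.13 CPM. Per kb of exon and over both libraries MT-ND6 held 3777 counts, MT-ND5 2217 and MT-ND4 1130, against 30.1 for the mitochondrial rRNA gene MT-RNR2. Since the strand setting is not given, it is uncertain which strand of the mitochondrial genome these reads came from. The list tests read counts as assigned to each gene. The strand of those reads is uncertain, and the strand comparison above leaned toward the opposite strand. A list that did not pass therefore cannot tell whether U2AF2 binds the RNAs of its genes. The splicing regulators did not pass the test. The 26 hnRNP genes had a median of 3.29 log2 CPM against 1.81 for random lists (adjusted permutation p = 0.119), and the 18 SR protein genes 3.20 against 1.78 (adjusted permutation p = 0.189). Among genes with at least 10 counts in each library these differences from random lists were -0.74 for 11 hnRNP genes and -0.44 for 7 SR protein genes, and among genes with no opposite-strand gene, a setting chosen after the data were seen, 12 SR protein genes passed with a difference of 1.56 (adjusted permutation p = 0.0450). HNRNPU held 526 ± 45.3 CPM, HNRNPAB 103 ± 1.51 CPM, SRSF9 80.4 ± 1.29 CPM and SRRM2 52.8 ± 18.6 CPM (SD, n = 2), and each of these 4 genes has a protein-coding gene on the opposite strand. HNRNPLL and SRSF3 held 0 counts in both libraries.

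Factors of 3' splice site recognition had a median of 1.60 log2 CPM against 1.85 for random lists (24 genes, adjusted permutation p = 0.707), led by CHERP with 45.4 ± 10.1 CPM (SD, n = 2). The 33 driver genes of myeloid malignancy had a median of 2.87 (adjusted permutation p = 0.157), with GATA2 at 386 ± 31.0 CPM, WT1 at 64.4 ± 5.48 CPM and JAK2 at 63.3 ± 3.89 CPM. The 12 genes whose splicing is reported to change in U2AF1-mutant cells had a median of 2.73 (adjusted permutation p = 0.556), led by ATG7 with 199 ± 17.2 CPM and GNAS with 142 ± 9.64 CPM. Intronless coding genes had a median of 2.42 (28 genes, adjusted permutation p = 0.119), with SOX12 at 65.7 ± 3.84 CPM. Ribosomal protein genes had a median of 1.68 (86 genes, adjusted permutation p = 0.664), with RPL10 at 269 ± 11.6 CPM and RPSA at 0 counts. Replication-dependent histone genes had a median of 1.37 (71 genes, adjusted permutation p = 0.353), with HIST1H4I at 201 ± 14.1 CPM. Stress granule proteins had a median of 2.33 (32 genes, adjusted permutation p = 0.580), with ATXN2 at 233 ± 16.5 CPM, and nonsense-mediated decay factors 2.49 (16 genes, adjusted permutation p = 0.580), with SMG6 at 17.6 ± 0.425 CPM. Of the genes given a CPM in this paragraph, all but HIST1H4I had an opposite-strand gene over their exons. It was protein-coding for CHERP (C19orf44), JAK2 (INSL6), ATG7 (VGLL4), RPL10 (DNASE1L1), ATXN2 (SH2B3) and SMG6 (HIC1). It was non-coding for GATA2, WT1, GNAS and SOX12.

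In all, 1 of 18 lists of coding genes stood above random lists and 0 stood below, and 4 had an unadjusted p below 0.05, namely mitochondrial mRNAs, hnRNP genes, intronless coding genes and myeloid drivers. Non-coding lists were described by values only. None of the 450 snoRNAs and scaRNAs except SNORA70G, which lies opposite RAP1B and held 36 and 48 counts, reached 10 counts in each library. The 32 spliceosomal snRNAs held 12 counts in each library in total, and the 11 measured 7SK, 7SL, Y, vault and RNase P/MRP RNAs held 0. Mitochondrial rRNAs and tRNAs held 385 and 580 counts in total, of which the tRNA gene MT-TQ held 248 and 407 and the large rRNA gene MT-RNR2 22 and 25. Among 24 long non-coding RNAs FTX led with 701 ± 61.2 CPM (SD, n = 2). Reads mapping to several places were outside the gene counts, so levels of any gene with near-identical copies, such as ribosomal protein, histone and small RNA genes, are uncertain.

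**Figure D4:**
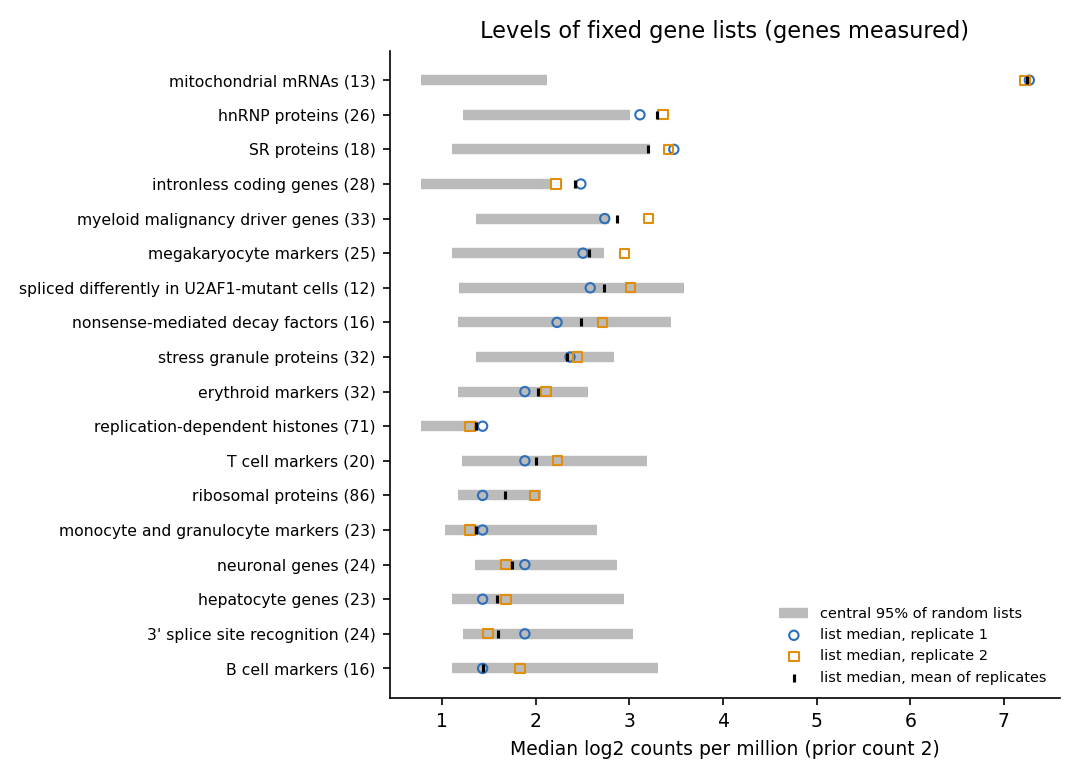
Median log2 CPM (horizontal axis, prior count 2) of each list of coding genes, with the number of genes measured in brackets; grey bars are the central 95% of 10000 random lists of protein-coding genes matched on gene span, circles and squares are replicates 1 and 2, and the black tick is the median over the mean of both. Mitochondrial mRNAs, at 7.25, lie apart from their bar.

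HEL is an erythroleukemia line, and the marker lists asked whether genes of its lineages held more counts than genes of other cell types. Here too the strand of the counted reads is uncertain, so a missing difference does not measure U2AF2 binding of these genes' RNAs. The 25 megakaryocyte markers had a median of 2.57 log2 CPM and the 32 erythroid markers 2.03. The medians were 1.37 for monocyte and granulocyte markers (23 genes), 2.00 for T cell markers (20 genes), 1.44 for B cell markers (16 genes), 1.75 for neuronal genes (24 genes) and 1.59 for hepatocyte genes (23 genes). Among single genes, the platelet receptor gene GP1BA held 310 ± 0.232 CPM (SD, n = 2), opposite CHRNE, the spectrin gene SPTB 285 ± 4.66 CPM, opposite PLEKHG3, the T cell factor gene TCF7 290 ± 29.6 CPM, opposite SKP1, and CA1, a carbonic anhydrase gene, 118 ± 17.1 CPM, opposite CA3. PF4, RHAG, SPI1 and STMN2 held 0 counts in both libraries.

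None of the 10 differences between a lineage list and another list passed the permutation test of list membership after adjustment, and 0 had an unadjusted p below 0.05. With the main settings, the largest was megakaryocyte minus monocyte and granulocyte markers, at 1.20 log2 CPM (1.07 in replicate 1 and 1.65 in replicate 2, permutation p = 0.0560, adjusted p = 0.259). Its size and sign under other settings are not reported here. The lowest adjusted p of an erythroid comparison was 0.525, against B cell markers, with a difference of 0.58 that was 1.24 with a prior count of 0.5, 0.28 without replicate 1 and -0.18 among genes with no opposite-strand gene, where all 5 erythroid differences were negative and none passed. Per kb of gene span, erythroid and megakaryocyte markers exceeded neuronal genes, which are long, by 5.17 and 4.19 on the log2 scale, with adjusted permutation p values of 0.0001 and 0.00055. No other lineage pair passed in that setting, and those differences are not reported here.

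Gene structure was compared because U2AF2 acts at introns. The strand of the counted reads is uncertain here as well, so the comparison does not measure U2AF2 binding of these genes' own RNAs. Single-exon protein-coding genes had a median of 0 counts over both libraries (1111 genes) and multi-exon genes a median of 5 (18661 genes). Their difference in median log2 CPM was -1.06, with a permutation p of 1e-05, the smallest that 100000 resamples can give, and its size depends on the prior count, since it was -2.37 with a prior count of 0.5. At least 10 counts in each library were held by 11.5% of single-exon and 25.7% of multi-exon genes. Opposite-strand genes lay over the exons of 25.4% of single-exon and 43.3% of multi-exon genes, and without them the difference was -0.61 with the same p. Across the 19772 protein-coding genes, log2 CPM had a Spearman rho of 0.329 with exonic length, 0.133 with gene span and 0.107 with intronic length. It was 0.228 with intron number, counted as gaps between merged exons, which can fall below the number of introns. For HNRNPU, merged exons covered 22512 of 23923 bases and left 3 gaps. Among genes with at least 10 counts in each library, the difference between single-exon and multi-exon genes was -0.32 with a permutation p of 0.0911, and the rho with exonic length was 0.0736.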

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

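The comparison of the exons of ribosomal, SR and hnRNP genes with the exons opposite to them was chosen only after the result was seen. The strand test was written down after the leading genes had been seen, though before their overlaps by strand were computed, and its form limited to introns was run after the broader ratio of 45.0 in the report had been seen. Uniquely mapped reads on no gene, which no comparison uses, numbered 36374618 in replicate 1 and 50621073 in replicate 2, far above the 3 counts that a count of 0 allows. They may hold intronic reads, which gene counting over exons leaves out, or reads of the strand that was not counted, and the table does not separate these. The strand ratio of 24.8 described next bears on the latter only.

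The pattern weighed was that the genes with the most counts mostly lay opposite a protein-coding gene, such as MFSD11 opposite SRSF2, AC037198.2 opposite THBS1 and AC006064.4 opposite GAPDH. Single-exon non-coding genes lying wholly in introns averaged 53.8 counts per kb where the intron belonged to an opposite-strand gene (2195 genes). They averaged 2.17 where it belonged to a same-strand gene (1684 genes). The ratio was 24.8 (95% bootstrap interval 18.6 to 33.6). For these genes as a set it argues against counting without regard to strand, since that would give a ratio near 1. It also argues against counting on their own strand, since a ratio below 1 was written down as the result without opposite-strand counting. A high level of the counted genes' own RNA was not settled by the planned test. In it, 47 ribosomal protein genes with no opposite-strand gene had a median at percentile 59.7 (29.6 to 70.3). Of 33 ribosomal, SR and hnRNP genes, only 1, RPL28, held more counts per kb of its own exons than was assigned to it per kb from the opposite strand (exact binomial p = 7.92e-09). The opposite-strand value divided the whole count of the opposite-strand genes by only their exon bases within the partner. That raises it where those genes extend further, so this split cannot decide the question. The strand ratio could arise from reads of a strand-specific library counted on the strand opposite to the bound transcript, a hypothesis under which counts of MFSD11 may come largely from SRSF2 RNA. It stays open how much of any single gene's count is its own RNA.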

How the results depend on the processing

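The settings that kept only genes with or without an opposite-strand gene, and all settings for counts read by the opposite-strand gene, were chosen only after the results were seen. Of 395 values recomputed under other settings, 359 stayed the same and 0 calls reversed; the same means the same call for lists and pairs, counts within 1.5-fold, and correlations within 0.05 for gene structure or within the bootstrap spread for replicates. Scaling by DESeq2 size factors or plain totals gave 47 and 48 genes that differ between replicates, against 45. With no count filter, 30752 genes held counts, 78 differed, Pearson r was 0.948 and Spearman rho 0.820; with at least 50 counts 3704 genes remained, r was 0.984 and rho 0.968. A prior count of 0.5 gave an r of 0.976, and genes with an opposite-strand protein-coding gene alone gave an r of 0.981 and a rho of 0.970. The DESeq2 dispersion corresponded to a median coefficient of variation of 0.252 over genes, and its fitted trend to a median of 0.260. The trended value of edgeR had a median of 0.0656 over the same genes. The size of the variation between replicates thus depends on the tool, and the cause was not tested. The number of lists above random lists was 0 without mitochondrial and small RNA genes, which removes the mitochondrial list itself, 4 among genes with no opposite-strand gene (adding SR proteins, myeloid drivers and histones), 2 when matched on exonic length (adding histones) and 2 when matched on intron number (adding intronless genes), and the cause was not tested. With at least 10 counts in each library, the difference from random lists fell to 2.00 for mitochondrial mRNAs and was -0.74 for hnRNP, -0.44 for SR, -0.62 for myeloid driver and -0.75 for intronless genes, none of these 4 past the threshold. Lineage pairs past the threshold numbered 2 per kb of gene span. With that filter, the rho with gene span was 0.0147 and with exonic length 0.0736, and the single-exon difference of -0.32 was no longer past the threshold, with fewer genes tested. Among genes with no opposite-strand gene these rho values were 0.186 and 0.380. Leaving out each replicate in turn gave a rho with exonic length of 0.277 to 0.315. The strand ratio was 36.7 with opposite-strand genes of any class and 44.4 to 45.8 with a replicate left out; with medians it had no value, since the same-strand median was 0 against 15.4. At a library total of 995428, genes below about 3 CPM cannot be told from absent. No paired analysis was possible because the samples form 1 group.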

Other observations

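The comparisons of lists by opposite-strand gene, and the test of mature mRNA by reads in introns, were chosen only after the results were seen; the lineage and splice site tests were written down after that pattern but before their results were seen, when TAL1 and THBS1 were already known to lie opposite leading genes. When the whole count of each gene with exactly 1 opposite-strand gene, a protein-coding one, was assigned to that partner, 7005 partners received 46.6% of all counts. Their median was 28.4 counts per kb over both libraries. Each count was divided only by the exon bases within the partner. Counts per kb in the list and lineage comparisons are therefore too high where a counted gene extends past its partner. For SON, all counts of DONSON, with 3513 exon bases, and of GART were divided by 1342 bases. The leading partners by counts were THBS1 with 4471 ± 115 CPM (SD, n = 2), GAPDH with 3588 ± 268 CPM, the mechanosensitive channel gene PIEZO1 with 3563 CPM (881 counts per kb), ZRANB2 with 3041 ± 332 CPM, AKAP8L with 2958 ± 21.9 CPM and TAL1, an erythroid transcription factor gene, with 2841 ± 146 CPM. Splicing regulators stood above random lists of partners, with medians of 1367 counts per kb for 5 SR protein genes and 873 for 13 hnRNP genes, led by SON with 3801 and HNRNPK with 4659 counts per kb. Ribosomal protein genes had a median of 541 (15 genes), with RPL10 at 2563 and RPL5 at 2503 counts per kb, although RPL5 held 3 counts on its own exons. For these 3 lists the adjusted p from random lists, a permutation test, was 0.00113, from the smallest p that 10000 lists can give.

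Genes of the HEL lineages were also high as partners. Erythroid markers had a median of 281 counts per kb (7 genes, adjusted permutation p = 0.0365), with TAL1 at 1656 and ZFPM1 at 648, and megakaryocyte markers 276 (10 genes, adjusted permutation p = 0.0136), with THBS1 at 19949, RAB27B at 3729, MEIS1 at 1153 and FLI1 at 672. RUNX1, another gene of that list, had 1.53 counts per kb. Stress granule proteins had a median of 163 (15 genes, adjusted permutation p = 0.0312), with ATXN2L at 2101 and PABPC4 at 1986. Neuronal genes had a median of 0, below random lists (17 genes, adjusted permutation p = 0.0017). T and B cell markers had medians of 0.341 and 0.794 without passing adjustment (adjusted permutation p = 0.0585 and 0.0745), and LEF1 stood out among T cell genes at 479 counts per kb. Of 17 lists tested, 6 stood above and 2 below, the latter including histones, whose call is not read because 4 of their 6 partners, such as HIST2H3A and HIST2H4B, belong to near-identical copies whose multimapping reads lie outside the counts. With replicate 1 left out 4 stood above and 1 below, and with replicate 2 left out 4 and 0. Erythroid markers (adjusted permutation p = 0.0640 without replicate 1 and 0.0504 without replicate 2) and stress granule proteins (0.108 and 0.0641) no longer passed with either replicate left out, nor neuronal genes without replicate 2 (0.0504). With non-coding counted genes only, 3 stood above and 0 below of 16, and the SR, hnRNP, erythroid and neuronal lists no longer passed (adjusted permutation p = 0.221, 0.0715, 0.0715 and 0.0715, from 3, 8, 5 and 15 partners). Megakaryocyte markers and ribosomal protein genes passed in every setting.

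The lineage test compared 17 erythroid and megakaryocyte partners, with a median of 281 counts per kb, with 38 partners from lists of other cell types, with a median of 0.723. The ratio was 388 with a lower bootstrap bound of 61.0, the permutation p was 1e-05, the smallest that 100000 resamples can give, and the fold is imprecise because its denominator lies near 0. Without TAL1 and THBS1 the ratio was 388 (15 partners, lower bound 48.6) with the same permutation p. This is consistent with reads from opposite-strand transcripts that HEL cells make. Without input libraries, RNA level and U2AF2 binding cannot be separated here.

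Whether these reads gathered at 3' splice sites of the partner was not settled. Genes whose exons met only a 3' splice site region had a median of 44.2 counts per kb (455 genes) and those that met only a 5' splice site region 30.5 (309 genes), a ratio of 1.45 (95% bootstrap interval 0.839 to 2.80, permutation p = 0.177). Genes wholly within partner exons had a median of 59.5 counts per kb (348 genes). This was 1.35 times the 3' splice site value (0.796 to 2.16, permutation p = 0.218). It was 7.77 times (5.19 to 10.2) the 7.66 of genes wholly within introns (5346 genes). Only the intronic side of splice sites was checked, so genes within exons may still lie next to one. By medians the planned test leaned toward genes within exons, within its spread. That class cannot separate mature partner mRNA from reads beside splice sites. Means went the other way, with 390 counts per kb for genes at a 3' splice site only and 278 for those within exons. The mean was 152 for genes at a 5' splice site only. Genes that met both kinds of region had a median of 60.6. The planned test therefore cannot decide between mature partner mRNA and crosslinking near 3' splice sites. Mature partner mRNA alone is argued against only by the later test of reads in introns, on a ratio already seen. There, single-exon non-coding genes opposite to the partner held 24.8 times (18.6 to 33.6) the counts per kb of those on its strand. Crosslinking near 3' splice sites stays open, since the interval of its ratio includes 1.

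Some genes with no opposite-strand gene in the annotation used here also held many counts, and they were chosen after their values were seen. The pseudogene AKAP8P1 held 1705 ± 6.02 CPM (SD, n = 2), MARCH1 1640 ± 145 CPM and MS4A2, a subunit gene of the IgE receptor, 1376 ± 26.6 CPM. The nuclear RNA NEAT1 held 2 counts in replicate 1 and 78 in replicate 2.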
